A study of Arabidopsis thaliana with 21 samples.

How the data were processed

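The values analysed were the deposited tables of log2 expression for 12 Affymetrix ATH1 arrays and 9 NimbleGen 12x135K arrays. Per the labels, RNA came from 3 independent biological samples per condition, was isolated with a column kit and was checked for degradation on a Bioanalyzer. ATH1 arrays were hybridised with biotin-labelled cRNA and NimbleGen arrays with Cy3-labelled cDNA, 1 sample per array. Per the submitters' processing notes the authors summarised the log2 values with RMA, whose version is not given in the sources used here. RMA corrects background, applies quantile normalization and fits a robust summary over the probes of each feature, so values are comparable between arrays of a table, a shift common to most transcripts is removed, and differences near the floor or the top of the scale are compressed. The tables were normalized separately and each was tested on its own. Time and platform differ together, so 1.5 h and 8 h were not compared.

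Groups and replicate numbers were taken from the labels, with 3 arrays in each of 4 ATH1 groups and 3 NimbleGen groups. No column of the tables was left unused. On ATH1, 64 control probe sets were left out of the main tests and 22746 probe sets were tested. Values given for control probe sets come from a second fit on all probe sets, controls included, with adjustment over all of them. All NimbleGen features were tested. They name 32627 loci, of which 31993 matched a locus tag in the RefSeq gene table (634 did not), and symbols and gene types were taken from there. No coordinates are given, because no genome build is named for the arrays. ATH1 probe sets were not paired with genes in the tables used here, so planned tests of the phosphate starvation list at 8 h and of the overlap of arsenate calls at 1.5 h and 8 h were not run.

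Each contrast was fitted with limma (version 3.58.1, R 4.3.3) on the deposited log2 values: lmFit over all groups of the table, contrasts.fit and eBayes, two-sided, with Benjamini-Hochberg adjustment per contrast and a call at an adjusted p under 0.05. No feature was filtered out. The standard errors printed are the moderated ones. Designs, alternatives, gene lists and the rule for named genes were set before the data were examined. The rule allowed WRKY6, WRKY42, WRKY45, WRKY75, PHT1;1, PHT1;4, PHO1, SPX1 and IPS1 always, the 8 genes each with the largest called increases and decreases whose groups did not overlap, up to 4 members of each list with the smallest adjusted p, and up to 5 transposable element loci each with the largest called rises and falls. On ATH1 up to 2 probe sets per direction were named by the same order. The text names part of these, and the second AT4G04223 feature and the second features of HSFA2, MAF4 and AT3G29644 were looked up after the values were seen. The feature used for HSFA2 in the heat list was the brighter one, with a rise of 5.06.

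Of 18 gene lists, 2 members (HAC1 and TIP41) were left out because the reference pairs their symbols with other loci. With the transposable element rule there were 19 sets. Each list took the brightest feature per gene and was tested with camera in limma, with a preset correlation of 0.01 and adjustment over the 19 sets of a contrast, and again with an estimated correlation. In the arsenate comparison at 1.5 h, 11 lists passed with the preset correlation and 1, the heat and chaperone list, with an estimated one. In the overexpressor comparison 5 passed and 0 did so with an estimated one. The transposable element rule searched annotation words and proved flawed: the given annotation holds only symbols, synonyms and gene types, and letters inside other words matched. Of its 46 loci, 16 are Sadhu retrotransposons and 30 are other genes. It was kept as planned, with the Sadhu loci as the planned stricter definition and loci typed pseudogene as one added after seeing the data. The Sadhu loci and the feature classes were tested as added sets, adjusted among themselves, and the Sadhu loci also in place of the rule, adjusted over the 19 sets.

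Correlations and overlaps between comparisons that share arrays were set beside 100 simulated pairs of unchanged groups for correlations and 20 for overlaps. These draws treat arrays as independent, so values for unchanged groups that keep the covariance of same-numbered arrays, from deviations from group means, were added after the data were seen. Whether replicate numbers pair the arrays was checked from deviations from group means: same-numbered arrays had to correlate above 0.1 in every pair. This held on NimbleGen (0.29 to 0.63) and among control, arsenate and 30 µM phosphate on ATH1 (0.13 to 0.49), but not for 1 mM phosphate (-0.2 to 0.07). The pairing comes from numbers in the sample titles, and the fit with the replicate number as a block is an alternative. The other alternatives were a further quantile normalization, centring on array medians, leaving out features below the 40 percentile of the table in all groups, a trended robust prior, only the compared groups, array weights, a minimum difference of 1 log2 unit, and leaving out each array in turn. Added later were features with a mean under 15, features without pseudogene, tRNA and organelle loci, and ATH1 without the replicate 1 arrays.

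The fit was tested on simulated data with 200 changed features per contrast. For arsenate against control at 1.5 h it recovered 34, 68, 90 and 100% of changes of 0.5, 1, 2 and 3 log2 units, with 6.41% false calls. For the overexpressor comparison it recovered 40, 68, 88 and 96%, with 5.19% false calls. The simulated arrays were independent and of equal spread within a feature. In the data same-numbered arrays correlated, and estimated weights of the overexpressor arrays ran from 0.39 to 6.81. Arsenate at 1.5 h also changed far more features (39.1% called). These rates thus check the fit and do not give the power or false-call rate of the real comparisons. RNA integrity was compared through the actin control of ATH1: the log2 difference of its 5' and 3' probe sets was -1.65 ± 0.24 in control, -1.61 ± 0.32 with arsenate, -1.55 ± 0.41 with 30 µM phosphate and -1.57 ± 0.14 with 1 mM phosphate (SD, n = 3).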

Results

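Transcript levels were measured in Arabidopsis thaliana plants of the Col-0 accession on 21 single-colour arrays. Per the labels, the plants spent 7 days on medium holding 1 mM phosphate and 2 days on medium lacking it, and were then moved to liquid medium. At 1.5 h, 3 groups of 3 independent biological samples were hybridised to a NimbleGen array: wild type without supplement, wild type with 30 µM arsenate, and plants labelled as overexpressing WRKY6 with 30 µM arsenate. At 8 h, 4 wild-type groups of 3 samples were hybridised to the Affymetrix ATH1 array, of which 22746 probe sets were tested: no supplement, 30 µM arsenate, 30 µM phosphate and 1 mM phosphate. The description field of the 1 mM phosphate samples reads 30 µM, whereas their title, source name and characteristics read 1 mM, and they were grouped as 1 mM. Arsenate is a structural analog of phosphate that enters plant cells through phosphate transporters. WRKY6 is a transcription factor known to act on phosphate transport genes. Array medians lay between 5.02 and 5.18 (log2) on ATH1 and between 12.33 and 12.42 on NimbleGen. Across features, replicate arrays of a group correlated with Pearson's r between 0.9804 and 0.9955. The number of arrays, 3 per group, limits the precision of every value.

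The first comparison asked what arsenate did to wild-type plants within 1.5 h. Heat shock genes were among those that rose most: HSFA2 (AT2G26150), a heat stress transcription factor, rose from 8.50 ± 0.25 to 15.49 ± 0.026 (log2 mean ± SD, n = 3), a difference of 6.98 ± 0.12 (SE, adjusted p = 4.8e-08). The second HSFA2 feature rose by 5.06. APX2 (AT3G09640), a cytosolic ascorbate peroxidase, rose by 6.72 ± 0.13 (adjusted p = 6.4e-08), and the small heat shock proteins HSP21 (AT4G27670) and HSP22 (AT4G10250) rose by 6.49 ± 0.15 and 6.35 ± 0.31. The 8 largest falls included those of EXPA14 (AT5G56320), an expansin, which fell by 4.14 ± 0.16 (adjusted p = 1.8e-06), and GRI (AT1G53130), which fell by 3.94 ± 0.14. FRO7 (AT5G49740) and FRO6 (AT5G49730), ferric chelate reductase genes, fell (-3.77 ± 0.23 and -3.53 ± 0.26). The multicopper oxidase-like gene sks16 (AT2G23630) fell by 3.65 ± 0.36. In all, 14517 features (39.1%) passed an adjusted p of 0.05, 7016 higher and 7501 lower, and 4508 of these differed by at least 1 log2 unit, 2640 higher and 1868 lower. The higher calls included 2157 pseudogene, 122 tRNA and 52 mitochondrial features, classes whose signal may not be transcripts, as described below. Of 30891 protein-coding features, 4334 were higher and 7239 lower. The arrays of both groups did not overlap for 55.2% of features, where chance gives 10% if arrays are independent. The count of 14517 fell to 9019 without wild-type arsenate replicate 1 and to 8959 without control replicate 3. It was 12227 with pseudogene, tRNA and organelle features left out. Centring each array on its median raised the share of higher calls from 48.3% to 59.7%. Several induced genes ended near the top of the scale (array maxima from 15.95), and HSFA2, APX2, HSP21 and HSP22 started below the lower quartile of the control arrays (9.40 to 9.49), so their differences are compressed and no folds are given.

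Of the 26 measured genes for heat shock proteins, their regulators and chaperones, 24 rose and 0 fell, with a median of 3.29 (adjusted p = 2.2e-26 in the list test, 0.0028 with an estimated correlation). HSP17.6C (AT1G53540) rose by 6.10 ± 0.096 and the mitochondrial HSP23.6 (AT4G25200) by 5.53 ± 0.079. Adjusted over the list alone, 25 rose. The list's median was 3.27 to 3.34 above the control mean on each of the 3 wild-type arsenate arrays. Of 25 oxidative stress genes, 12 rose and 0 fell, and adjusted over the list alone also 12 and 0 (median 0.21, adjusted p = 0.00095, 0.06 with an estimated correlation). The median was 0.379 without arsenate replicate 1, 0.0615 without arsenate replicate 3 and 0.358 without control replicate 3, and the list passed each time. Besides APX2 they included the zinc finger gene ZAT12 (AT5G59820), up by 3.44 ± 0.097, and the kinase gene OXI1 (AT3G25250), up by 2.33 ± 0.11.

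Several genes of hormone and immunity pathways rose. Of 23 jasmonate genes, 17 rose and 0 fell (median 0.58, adjusted p = 3.9e-09, 0.06 with an estimated correlation), among them the repressor genes JAZ7 (AT2G34600), by 3.72 ± 0.18, and JAZ10 (AT5G13220), by 3.02 ± 0.12, and the lipoxygenase LOX3 (AT1G17420), by 2.59 ± 0.15. Adjusted over the list alone, 17 rose and 1 fell. Of 13 ethylene genes, 10 rose and 0 fell, also when adjusted over the list alone (median 0.83, adjusted p = 4.8e-06, 0.06 with an estimated correlation). ERF6 (AT4G17490), an ethylene response factor, rose by 2.35 ± 0.12, and ACS6 (AT4G11280), an enzyme of ethylene synthesis, by 1.08 ± 0.093. Of 15 immunity genes, 5 rose and 1 fell, with the same counts adjusted over the list alone (median 0.22, adjusted p = 0.024, 0.53 with an estimated correlation). NHL10 (AT2G35980) rose by 2.18 ± 0.13 and PAD3 (AT3G26830), an enzyme of camalexin synthesis, by 0.98 ± 0.19. The immunity list had an adjusted p of 0.054 on the compared groups only, 0.055 without arsenate replicate 1 and 0.063 without control replicate 2.

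Among genes of sulfur and thiol metabolism, 13 of 26 sulfur assimilation genes rose and 2 fell, also when adjusted over the list alone (median 0.16, adjusted p = 0.01, and p = 0.36 with an estimated correlation). BGLU28 (AT2G44460), a glucosidase gene of sulfur deficiency, rose by 3.21 ± 0.40, the ATP sulfurylase APS3 (AT4G14680) by 1.21 ± 0.085 and the serine acetyltransferase SERAT2;1 (AT1G55920) by 0.68 ± 0.062, while the sulfate transporter SULTR2;2 (AT1G77990) fell by 1.71 ± 0.21. Of 35 glutathione S-transferases, 14 rose and 8 fell (15 and 8 adjusted over the list alone), among them GSTU12 (AT1G69920) with 3.69 ± 0.12 and GSTU6 (AT2G29440) with 2.56 ± 0.14. That list had a median of 0.10 (0.152 without control replicate 2) and passed narrowly (adjusted p = 0.045). It did not pass with an estimated correlation (adjusted p = 0.41), with the replicate number as a block (0.073), after median centring (0.062), on the compared groups only (0.092), or without arsenate replicate 1 (0.055), arsenate replicate 2 (0.098) or control replicate 3 (0.078). Of 16 genes for arsenic, glutathione and phytochelatin handling, 1 rose and 4 fell, also when adjusted over the list alone (median -0.15, -0.0922 without arsenate replicate 3 and -0.0887 without control replicate 3, adjusted p = 0.36, 0.56 with an estimated correlation). The aquaporin-like channel NIP2;1 (AT2G34390) rose by 3.07 ± 0.28, and the related NIP1;1 (AT4G19030) and NIP6;1 (AT1G80760) fell (-1.02 ± 0.076 and -1.01 ± 0.16).

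Several pigment, growth and root genes fell. Of 16 anthocyanin and flavonoid genes, 9 fell and 0 rose (median -1.05, adjusted p = 0.00041, 0.36 with an estimated correlation), including UF3GT (AT5G54060, -1.82 ± 0.37) and the regulators PAP1 (AT1G56650, -1.63 ± 0.18) and MYB12 (AT2G47460, -1.19 ± 0.15). Of 16 root and root-hair markers, 9 fell and 0 rose (median -0.83, adjusted p = 0.0011, 0.3 with an estimated correlation): RHD6 (AT1G66470), a root-hair regulator, fell by 2.04 ± 0.23, and the root meristem regulators PLT1 (AT3G20840) and PLT2 (AT1G51190) fell (-1.45 ± 0.22 and -1.42 ± 0.22). SHR (AT4G37650) fell by 0.97 ± 0.10. Adjusted over the list alone, both lists kept 9 lower and 0 higher. Of 18 cell cycle genes, 11 fell and 0 rose (median -0.44, adjusted p = 6.1e-05, 0.3 with an estimated correlation, with 12 lower and 0 higher adjusted over the list alone), and the cyclins CYCA1;1 (AT1G44110) and CYCD3;1 (AT4G34160) fell (-1.50 ± 0.13 and -1.06 ± 0.14).

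Lists that did not pass held single movers. Of 10 DNA damage genes, 1 rose and 2 fell (1 and 4 adjusted over the list alone, median -0.30, -0.176 without arsenate replicate 1, adjusted p = 0.23, 0.44 with an estimated correlation). The cell cycle inhibitor gene SMR5 (AT1G07500) rose by 2.36 ± 0.22, and its relative SMR7 (AT3G27630) and the ribonucleotide reductase gene TSO2 (AT3G27060) fell (-1.17 ± 0.15 and -1.11 ± 0.17). Of 21 iron deficiency genes, 2 rose and 6 fell, also when adjusted over the list alone (median -0.22, -0.358 without arsenate replicate 3 and -0.33 without control replicate 1, adjusted p = 0.083, 0.043 without control replicate 1, 0.41 with an estimated correlation), and the regulator BHLH38 (AT3G56970) and the nicotianamine synthase NAS1 (AT5G04950) fell (-1.63 ± 0.36 and -1.15 ± 0.18). Of 25 photosynthesis genes, markers of green tissue, 0 rose and 2 fell (0 and 1 adjusted over the list alone, median -0.03, -0.0201 without control replicate 2, adjusted p = 0.24, 0.61 with an estimated correlation). LHCB2.2 (AT2G05070) fell by 1.11 ± 0.23, and 21 of the 25 lay near the top of the scale. None of the 7 measured reference genes was called, with 0 adjusted over the list alone (median -0.02, adjusted p = 0.96, 0.97 with an estimated correlation). Of these 7, 5 lay near the top of the scale, where differences are compressed. Centring on array medians turned the medians of the photosynthesis and reference lists positive (0.0437 and 0.0567) and moved those of the iron, arsenic handling and silencing lists to -0.14, -0.0719 and -0.114. The reference median was -0.0087 and 0.0042 without arsenate replicates 1 and 2 and 0.0109 without control replicate 1.

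**Figure D1:**
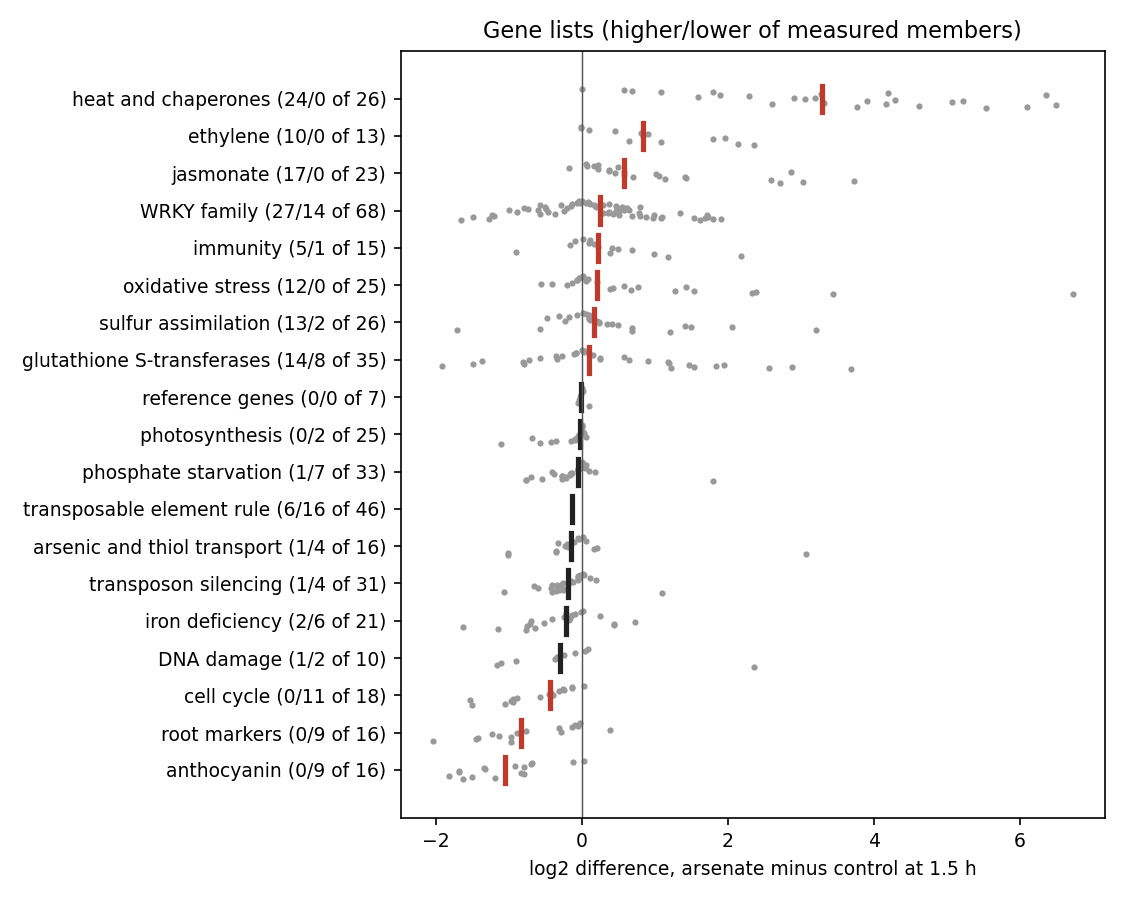
Log2 differences of the members of each gene list between wild type with arsenate and wild type without supplement at 1.5 h. Each grey point is 1 gene, the vertical bar is the list's median, red where the list test passed an adjusted p of 0.05 with the preset correlation and black where it did not, and members of the transposable element rule are not drawn. The heat and chaperone list lies furthest to the right, with a median of 3.29.

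WRKY6 (AT1G62300) rose with arsenate at 1.5 h by 0.29 ± 0.063, from 15.55 ± 0.058 to 15.84 ± 0.015 (n = 3, adjusted p = 0.01). This feature lay above 92.7% of all features on every array, so the size of its rise is compressed. Of the 68 measured WRKY genes, 27 rose and 14 fell (29 and 16 adjusted over the list alone). WRKY30 (AT5G24110) rose by 1.90 ± 0.15 and WRKY75 (AT5G13080), a regulator in phosphate starvation, by 1.80 ± 0.14, while WRKY71 (AT1G29860) fell by 1.66 ± 0.12. The WRKY list had a median of 0.24 (adjusted p = 0.024), with an adjusted p of 0.56 with an estimated correlation, 0.057 after median centring, 0.055 on the compared groups only, 0.055 without arsenate replicate 1 and 0.062 without control replicate 2. WRKY45 (AT3G01970) differed by 0.47 ± 0.15 (adjusted p = 0.035), a call lost on leaving out any 1 of the 6 arrays (adjusted p 0.051 to 0.12). WRKY42 (AT4G04450) differed by -0.79 ± 0.29 without passing (adjusted p = 0.061), and it passed with the replicate number as a block (adjusted p = 0.0023) and without control replicate 2 (0.034).

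Genes induced by phosphate starvation had a high signal in these plants, and 19 of the 33 on the list had a mean over all arrays near the top of the scale. Of the 33, 1 rose and 7 fell (1 and 3 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.083, 0.53 with an estimated correlation). The adjusted p was 0.031 without arsenate replicate 1, and median centring turned the median to 0.02. WRKY75 was the member that rose. PHO1;H1 (AT1G68740), a homologue of the phosphate exporter PHO1, fell by 0.77 ± 0.14 and the phosphate transporter PHT1;7 (AT3G54700) fell by 0.76 ± 0.18. The main uptake transporters PHT1;1 (AT5G43350) and PHT1;4 (AT2G38940) differed by -0.16 ± 0.063 (adjusted p = 0.081, 0.045 with array weights) and -0.06 ± 0.064 (0.48), and the phosphate sensor gene SPX1 (AT5G20150) by -0.05 ± 0.065 (0.61). PHO1 (AT3G23430) fell by 0.47 ± 0.13 (adjusted p = 0.024), a call lost without arsenate replicate 1 (0.077) or 2 (0.073) or control replicate 1 (0.073) or 3 (0.06). The noncoding RNA gene IPS1 (AT3G09922) fell by 0.23 ± 0.074 (adjusted p = 0.041). That call was lost after median centring (0.13), on the compared groups only (0.062) and without arsenate replicate 1 (0.058), 2 (0.091) or 3 (0.12) or control replicate 1 (0.1) or 3 (0.12).

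The title of the series names transposon activation, so transcripts of transposable elements were compared next. Of the 16 Sadhu retrotransposon loci, 3 rose and 3 fell with arsenate (3 and 3 adjusted over the list alone, adjusted p = 0.7 among the added sets and 0.74 over the 19 sets, 0.81 with an estimated correlation), and the median (-0.01) differed in sign from the mean (0.11). SADHU9-1 (AT1G44935) rose by 0.97 ± 0.14 and SADHU8-1 (AT1G50735) by 0.89 ± 0.15. Both started low, at 9.31 and 9.01, below the lower quartile of the control arrays (9.40 to 9.49). The 3 Sadhu loci that fell are not among those the rule for named genes gives. The rule fixed for transposable elements took 46 loci, of which 30 are other genes, and of the 46, 6 rose and 16 fell (7 and 16 adjusted over the list alone, median -0.13, adjusted p = 0.1, 0.36 with an estimated correlation). Fisher's exact test gave p = 0.35 for members among the higher features and 0.016 among the lower. The 16 Sadhu loci do not stand for transposable elements at large. Loci that RefSeq types as pseudogenes include transposon copies, among them SADHU9-1 and SADHU8-1, in a number the annotation does not give. They were taken separately, and their signal was low (median level 9.4 over all arrays). Of 3858 such loci, 2155 rose and 31 fell (2413 and 35 adjusted over the class alone), with a median of 0.60 (adjusted p = 1.7e-24, 0.5 with an estimated correlation). With it rose tRNA loci (122 of 169, median 1.06, 0.5 with an estimated correlation) and mitochondrial loci (52 of 107, median 0.73, 0.5). Of 87 chloroplast loci 0 were called (median 0.04, 0.03 to 0.06 on the 3 arsenate arrays), but 78 of them lay near the top of the scale. The labels do not say whether genomic DNA was removed from the RNA, so signal from DNA cannot be set apart from transcripts of these classes. The classes were added after the data were examined. On the 3 arsenate arrays the pseudogene class lay 0.56 to 0.64 above the control mean, and on control replicate 2 it lay 0.15 above. tRNA loci lay 0.90 to 1.21 above it on the arsenate arrays and from -0.39 to 0.47 on the controls. For mitochondrial loci these values were 0.61 to 0.78 and -0.35 to 0.33. Members of both classes moved together (estimated correlation 0.85 for tRNA and 0.67 for mitochondrial loci), so their counts are not separate results. Among 31 genes of the silencing machinery, 1 rose and 4 fell (1 and 1 adjusted over the list alone, median -0.19, -0.287 without arsenate replicate 3, adjusted p = 0.066). The Argonaute gene AGO2 (AT1G31280) rose by 1.09 ± 0.11 and the RNA-dependent RNA polymerase RDR2 (AT4G11130) fell by 1.07 ± 0.18. The silencing list passed with the replicate number as a block (adjusted p = 0.018), without arsenate replicate 3 (0.0045) and without control replicate 1 (0.034), and had an adjusted p of 0.61 with an estimated correlation.

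The second comparison asked how plants labelled as WRKY6 overexpressors differed from wild type when both had 30 µM arsenate for 1.5 h. The WRKY6 feature read 15.83 ± 0.036 in them and 15.84 ± 0.015 in wild type (n = 3 each, difference -0.01 ± 0.063, adjusted p = 0.99). Near the top of the scale it cannot check the label, so the arrays are called by their label throughout. MAF4 (AT5G65070), a repressor of flowering, was higher, at 10.76 ± 0.28 against 8.92 ± 0.20 (log2 difference 1.85 ± 0.15, adjusted p = 0.018). The long noncoding RNA locus AT3G29644 was higher by 1.22 ± 0.086 (adjusted p = 0.016), and the noncoding RNA locus AT4G04223 was lower, with a difference of -1.99 ± 0.15 (adjusted p = 0.018). Each of the 3 overexpressor arrays lay apart from all 3 wild-type arsenate arrays for these loci. The second AT4G04223 feature was also lower (-1.29, adjusted p = 0.018), but second features of MAF4 (0.024, adjusted p = 0.97) and AT3G29644 (0.34, adjusted p = 0.57) were not called.

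These 4 features, 2 higher and 2 lower, were the only calls with limma among the NimbleGen features, and 2833 had an unadjusted p under 0.05. Arrays of both groups did not overlap for 10.5% of features, where chance gives 10% if arrays are independent. Same-numbered arrays of these groups correlated, so 10% is only a rough mark. The count was 0 when fitted on the compared groups only, where the adjusted p of each named locus was 0.2, and 12 (8 higher, 4 lower) with the replicate number as a block. Leaving out single arrays gave 0 without overexpressor replicate 3 or wild-type replicate 1 or 3, 1 without wild-type replicate 2, and 105 without overexpressor replicate 2. Without overexpressor replicate 3 and wild-type replicates 1, 2 and 3 in turn, the adjusted p was 0.079, 0.076, 0.15 and 0.16 for MAF4, 0.071, 0.076, 0.037 and 0.11 for AT3G29644, and 0.071, 0.14, 0.13 and 0.11 for AT4G04223. With estimated array weights it was 5690, where overexpressor replicate 3 had a weight of 6.81 against 0.41 and 0.39 for the others of its group. No feature was higher with arsenate and lower in the overexpressor (1 with the replicate block), and 1 was higher in both comparisons, where independent lists give 0.378. Simulated unchanged groups gave 0, but groups without change hold few calls to share, so this sets no mark. The comparisons share the wild-type arsenate arrays with opposite sign. Their log2 differences correlated with r = -0.61 across features against -0.5 simulated, with a covariance of -0.1 against -0.018. Unchanged groups that keep the pairing of same-numbered arrays gave -0.53 and -0.011. The shared arrays could not be split, and part of the excess may come from them. No overexpressor array without arsenate was analysed here, so genotype and its interaction with arsenate cannot be separated.

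**Figure D2:**
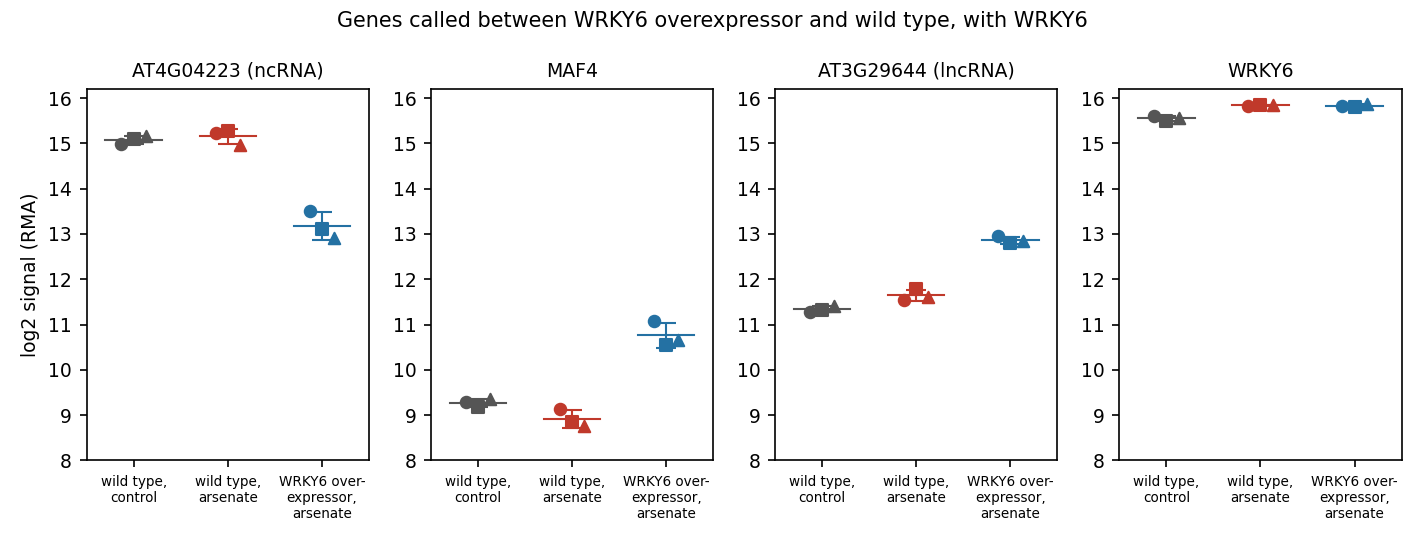
Log2 RMA signal of the 3 loci called between WRKY6 overexpressor and wild type under arsenate at 1.5 h, and of WRKY6, on each array. Each marker is 1 array (circle, square and triangle for replicates 1, 2 and 3), the long line is the group mean and the bars are 1 SD. MAF4 lies at 10.76 in the overexpressor against 8.92 in wild type, and WRKY6 lies at 15.83 against 15.84.

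No member of any gene list was called between the overexpressor and wild type under arsenate. Only 4 features (0.0108%) were called at all, so this does not show that gene groups were unchanged. Immunity genes were lower by the list test with the preset correlation (median -0.24, adjusted p = 0.00077) but not with an estimated correlation (0.6), with the glucanase PR2 (AT3G57260) at -0.66 ± 0.14 (adjusted p = 0.38). Jasmonate genes had a median of -0.07 (adjusted p = 0.046, 0.6 with an estimated correlation), with the defensin PDF1.2A (AT5G44420) at -1.18 ± 0.32 (adjusted p = 0.49). Cell cycle genes (median 0.14, adjusted p = 0.00043), root markers (0.23, 0.0028) and iron deficiency genes (0.11, 0.0043) were higher by the list test, but not with an estimated correlation (adjusted p = 0.51 each). NAS4 (AT1G56430) differed by 0.81 ± 0.11 (adjusted p = 0.13, 0.046 without overexpressor replicate 2), and CYCB2;2 (AT4G35620) by 0.88 ± 0.25 (adjusted p = 0.52). With array weights NAS4 (adjusted p = 0.003), PR2 (0.011), PDF1.2A (0.014) and CYCB2;2 (0.014) passed. That fit called 5690 features and rested mainly on overexpressor replicate 3 (weight 6.81 against 0.41 and 0.39), so it lends these genes little weight. The immunity call was lost without overexpressor replicate 2 (0.29), the iron call without wild-type replicate 1 (0.066) and without dim features (0.29), and the root call without wild-type replicate 2 (0.14). Medians also moved: immunity to -0.143 and -0.152 without overexpressor replicate 2 or 3 and -0.161 without wild-type replicate 3, jasmonate to -0.0279 without overexpressor replicate 2 and -0.0274 without wild-type replicate 1, and cell cycle to 0.213 without wild-type replicate 3. Iron moved to 0.161 without overexpressor replicate 1 and to 0.0379, 0.234 and 0.227 without wild-type replicates 1, 2 and 3, and root to 0.114 without overexpressor replicate 3 and 0.127 without wild-type replicate 2. The jasmonate call was lost without overexpressor replicate 2 (0.72) and wild-type replicates 1 (0.26) or 2 (0.052). Adjusted over the list alone, 1 immunity gene was lower, and 1 iron and 1 arsenic handling gene were higher, with 0 in the jasmonate, cell cycle and root lists.

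The remaining lists did not pass between overexpressor and wild type, with 0 members called and 0 adjusted over the list alone except where given. Median differences were 0.01 for phosphate starvation (adjusted p = 0.9), 0.01 for arsenic handling (0.58), 0.03 for glutathione S-transferases (0.36) and 0.04 for the silencing machinery (0.58). These 4 medians turned negative after median centring (-0.0243, -0.0244, -0.0107 and -0.00182). Medians of 0 were found for the heat (adjusted p = 0.9), sulfur (0.59) and oxidative lists (0.9), 0.04 for ethylene (0.59), -0.01 for WRKY genes (0.59), 0.07 for anthocyanin (0.64), -0.01 for photosynthesis (0.82), 0.19 for DNA damage (0.12) and 0.02 for reference genes (0.89, -0.0156 after median centring). Without overexpressor replicates 1, 2 and 3 and wild-type replicates 1, 2 and 3 in turn, the median was 0.219, -0.0191, -0.0424, -0.125, 0.135 and 0.228 for anthocyanin, -0.0634, 0.0277, -0.0266, 0.0107, -0.0435 and -0.0263 for WRKY genes, and 0.101, 0.078, -0.0526, 0.0152, -0.0352 and 0.149 for silencing. That for DNA damage was 0.124 without overexpressor replicate 3 and 0.0716 without wild-type replicate 1, and that for ethylene 0.0217 without overexpressor replicate 1. The other medians, all close to 0, also moved with single arrays. The phosphate starvation median went from -0.0147 (without wild-type replicate 2) to 0.0393 (wild-type 1), arsenic handling from 0.00707 (overexpressor 3) to 0.0535 (overexpressor 2), and glutathione S-transferases from 0.00808 (overexpressor 1) to 0.0694 (wild-type 2). Heat went from -0.012 (overexpressor 2) to 0.0104 (overexpressor 1), sulfur from -0.0119 (wild-type 3) to 0.0317 (wild-type 2) and oxidative from -0.0116 (overexpressor 2) to 0.00718 (overexpressor 3). Photosynthesis went from -0.0262 (wild-type 1) to 0.00397 (overexpressor 1), and the reference median was lowest at 0.00517 (wild-type 2). DNA damage genes passed with the replicate number as a block (adjusted p = 0.033), without overexpressor replicate 1 (0.029) and without wild-type replicate 3 (0.017). Silencing genes passed without overexpressor replicate 1 (0.022) and without wild-type replicate 3 (0.0016), and WRKY and anthocyanin genes without overexpressor replicate 1 (0.019 and 0.029). WRKY genes also passed without dim features (0.046). Of the phosphate transport genes, PHO1 differed by 0.02 ± 0.13 (adjusted p = 0.99), PHT1;1 by 0.01 ± 0.063 (0.99) and PHT1;4 by 0.03 ± 0.064 (0.94).

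Transposable element loci were compared between overexpressor and wild type in the same way. For the 46 loci of the fixed rule the median was 0.01, the mean -0.04 and the test pointed down (adjusted p = 0.58), with 0 called and 4 lower adjusted over the list alone. The 16 Sadhu loci had a median of -0.17 (adjusted p = 2e-08 among the added sets and 2.6e-07 over the 19 sets), with 0 called and 6 lower adjusted over the list alone. With an estimated correlation the adjusted p was 0.023 among the added sets and 0.072 over the 19. The 3 overexpressor arrays had Sadhu medians of -0.15, -0.28 and -0.07 against the control mean, and the 3 wild-type arsenate arrays 0.04, -0.03 and 0.01. Pseudogene loci had a median of -0.30 (adjusted p = 5.9e-33, 0.29 with an estimated correlation), with 0 called and 2 lower adjusted over the class alone. The overexpressor arrays differed widely for this class: replicate 1 lay at -0.02 against the control mean, replicate 2 at 0.69 and replicate 3 at 0.27. tRNA loci (0.02, 1.19 and 0.21) and mitochondrial loci (-0.05, 0.85 and 0.39) were ordered in the same way, whereas the heat list lay at 3.23, 3.32 and 3.33.

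**Figure D3:**
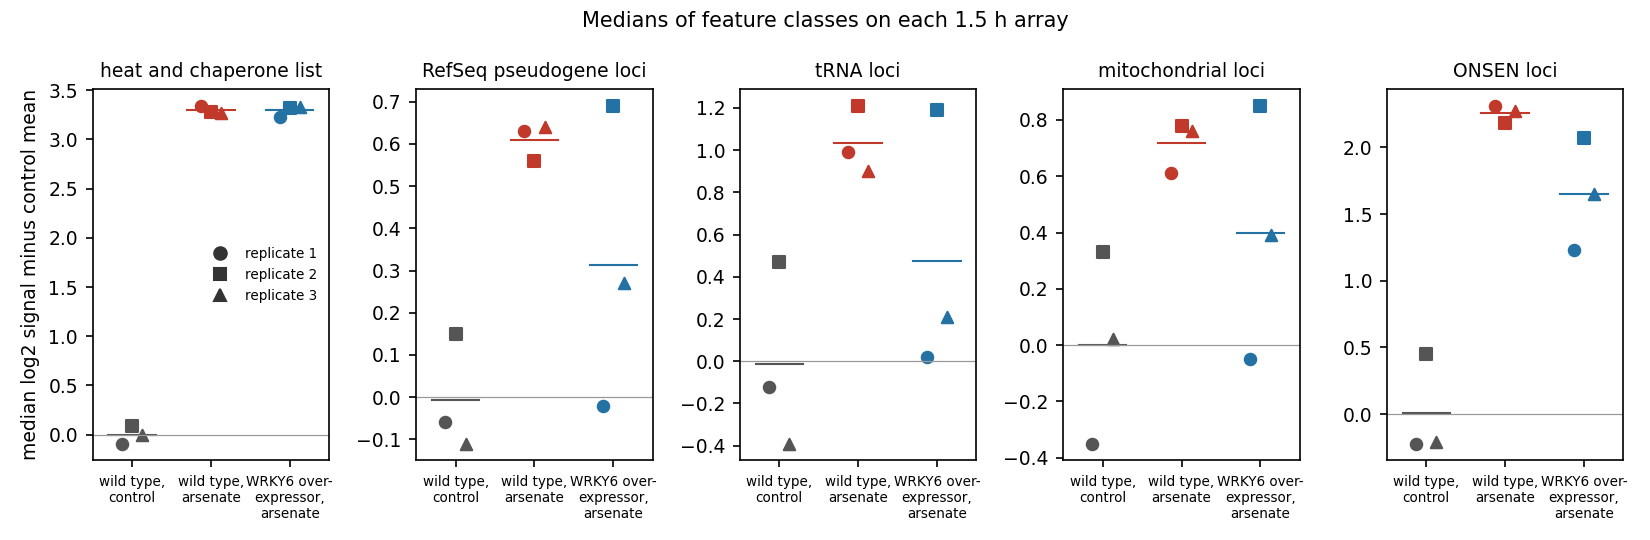
Median log2 signal of feature classes on each 1.5 h array, relative to the mean of the control arrays. Each marker is 1 array (circle, square and triangle for replicates 1, 2 and 3), the line is the group mean and each panel has its own vertical scale. The pseudogene class lies at -0.02, 0.69 and 0.27 on the 3 overexpressor arrays, while the heat and chaperone list lies between 3.23 and 3.34 on all 6 arsenate arrays.

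At 8 h, the third comparison asked what 30 µM arsenate did to wild type. ATH1 probe sets are not paired with genes in the tables used here, so single probe sets are given by their identifier. Probe set 250351_at was higher with arsenate, at 12.72 ± 0.10 against 3.50 ± 0.24 (log2 difference 9.21 ± 0.12, n = 3, adjusted p = 6.5e-13), and 260978_at was higher by 8.52 ± 0.22. The control signal of 250351_at lay below the lower quartile of the control arrays (3.64 to 3.72), so no fold is given. Probe set 254820_s_at fell by 6.39 ± 0.19 and 260234_at fell by 5.23 ± 0.37. Of 22746 probe sets, 5469 (24%) passed, 2465 higher and 3004 lower, and 2119 differed by at least 1 log2 unit, 1211 higher and 908 lower. The array's own control probe sets carry gene names: all 5 for GAPDH, a glycolytic enzyme, were higher with arsenate (0.40 to 0.82, adjusted p 0.00018 to 0.0039), as were all 5 for ubiquitin (0.35 to 0.56, adjusted p 0.0016 to 0.04). The 6 for actin differed by -0.13 to -0.05 (adjusted p 0.66 to 0.94). The calls for GAPDH and ubiquitin held under both other scalings.

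**Figure D4:**
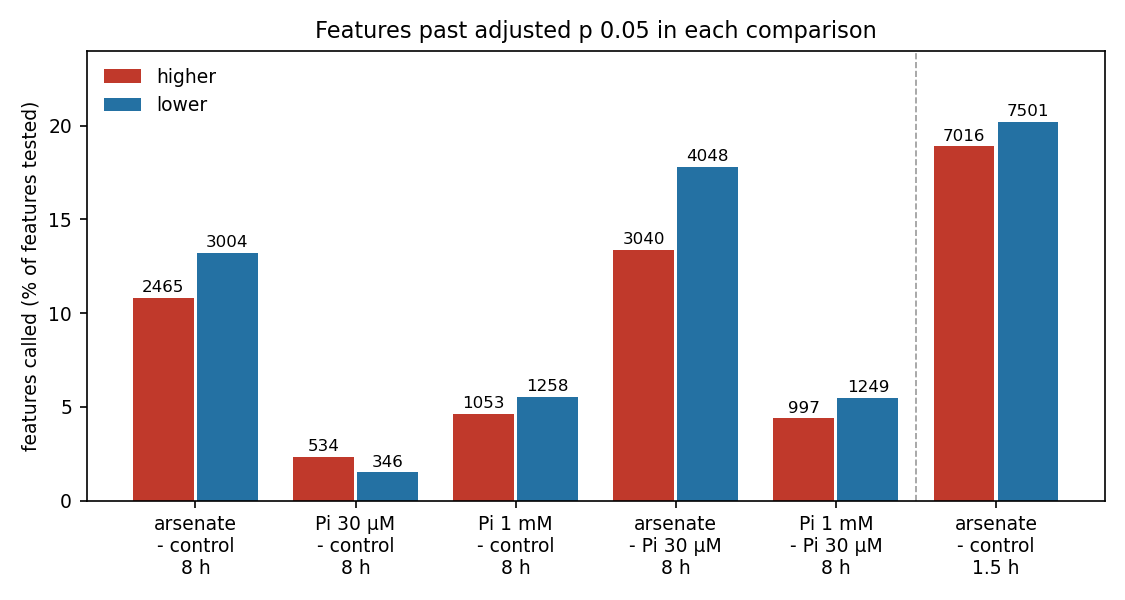
Share of features called higher (red) and lower (blue) at an adjusted p of 0.05 in each comparison without the overexpressor, as a percent of features tested, with the number of features above each bar. The dashed line parts the 8 h comparisons on ATH1 from the 1.5 h comparison on NimbleGen. Arsenate gave 5469 calls at 8 h against control and 30 µM phosphate gave 880.

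Resupply of 30 µM phosphate for 8 h changed fewer probe sets. Probe set 259842_at rose by 2.42 ± 0.22 (5.35-fold, adjusted p = 0.00094) and 246303_at by 1.96 ± 0.28, while 260097_at fell by 3.41 ± 0.35 and 250091_at fell by 2.75 ± 0.35. In all, 880 probe sets passed, 534 higher and 346 lower, and of the 224 that differed by at least 1 log2 unit 69 were higher and 155 lower. The share of higher calls moved from 60.7% to 50.9% with median centring. GAPDH (-0.26 to -0.12), ubiquitin (-0.25 to -0.11) and actin (0.13 to 0.31) control probe sets were not called. The count depended on single arrays: it was 477 and 259 without phosphate replicate 2 or 3, 287 and 335 without control replicate 2 or 3, 2377 with estimated array weights, and 1876 without the replicate 1 arrays of all groups, an alternative chosen after seeing the data.

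Resupply of 1 mM phosphate lowered some probe sets to near the bottom of the scale. Probe set 262369_at fell by 7.82 ± 0.31, from 11.72 ± 0.17 to 3.90 ± 0.17 (n = 3, adjusted p = 1.1e-07), and 263391_at fell by 6.51 ± 0.27. Probe set 259842_at rose by 3.05 ± 0.22, and 257365_x_at rose by 2.58 ± 0.52. In all, 2311 probe sets passed, 1053 higher and 1258 lower, and of the 592 that differed by at least 1 log2 unit 161 were higher and 431 lower. The share of higher calls moved from 45.6% to 53.2% with a further quantile normalization and to 52.6% with median centring. Of the 5 GAPDH control probe sets (-0.48 to -0.09), 2 were called lower. The count was 1247 without 1 mM phosphate replicate 1, 1366 without control replicate 1 and 1413 without control replicate 3. Of the 439 probe sets called with both phosphate doses, 160 were higher and 277 lower with both and 2 were opposite, where independent lists give 43.9 in the same direction and 45.6 opposite. The log2 differences of both doses correlated with r = 0.51 across probe sets. Unchanged groups against the same controls gave r = 0.5, and the covariance was 0.068 against a simulated 0.017 (r = 0.29 and 0.007 with same-numbered arrays kept paired). The 3 control arrays could not be split, so part of the overlap may come from them.

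The doses were also compared with each other. Probe set 262373_at was higher with 1 mM than with 30 µM phosphate by 3.35 ± 0.42 (adjusted p = 0.0018) and 266141_at by 2.18 ± 0.34, while 262369_at fell by 6.13 ± 0.31 and 259399_at fell by 4.66 ± 0.33. In all, 2246 probe sets passed, 997 higher and 1249 lower, and of the 444 that differed by at least 1 log2 unit 217 were higher and 227 lower. The share of higher calls moved from 44.4% to 54.8% with a further quantile normalization and to 64.9% with median centring, which shifted the median difference of all probe sets to 0.12. The count was 680, 1407 and 1100 without 1 mM replicate 1, 2 or 3, and 863 and 1193 without 30 µM replicate 1 or 3.

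Arsenate and phosphate, which differ in their central atom, were compared directly at 30 µM and 8 h. Probe set 250351_at was higher with arsenate than with phosphate, by 9.39 ± 0.12 (n = 3, adjusted p = 5.2e-13), and 260978_at was higher by 8.77 ± 0.22, while 254820_s_at fell by 6.59 ± 0.19 and 260234_at fell by 4.67 ± 0.37. GAPDH and ubiquitin control probe sets were higher with arsenate than with phosphate (0.66 to 0.99, adjusted p 1.6e-05 to 0.00043, and 0.50 to 0.75, adjusted p 0.00014 to 0.0039). Of 22746 probe sets, 7088 (31.2%) differed, 3040 higher and 4048 lower with arsenate, and of the 2724 that differed by at least 1 log2 unit 1435 were higher and 1289 lower. The share of higher calls moved from 42.9% to 50.3% with median centring. Of the 345 probe sets called against control with both compounds, 96 changed in the same direction and 249 in opposite directions, where independent lists give 104 and 108. Across probe sets the effects of both compounds correlated with r = 0.021, against 0.5 for unchanged groups sharing the same controls, and their covariance was 0.0046 against a simulated 0.017. With same-numbered arrays kept paired, unchanged groups gave r = 0.47 and a covariance of 0.011. Arsenate and 1 mM phosphate, which differ in dose, shared 942 called probe sets, 338 in the same direction and 604 opposite, where independent lists give 280 and 275 (r = -0.043, covariance -0.014, against 0.28 and 0.0073 with same-numbered arrays kept paired). Simulated unchanged groups shared 0 calls, but groups without change hold few calls to share, so this sets no mark for either overlap. Neither overlap could be tested with separate sets of control arrays.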

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

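A control probe set of the ATH1 design, outside the probe sets of the main tests, read 8.09 (log2) on replicate 1 of the 8 h arsenate group and 8.07 on replicate 1 of the 30 µM phosphate group. On the other 10 arrays it read 3.31 to 3.78. It is listed because a signal appeared in data outside the comparisons, above the level in the control arrays. On those 2 arrays the actin control also differed, with a 5' minus 3' log2 difference of -1.24 and -1.11 against -1.93 to -1.42 on the other 10. No explanation was tested. Replicate 1 arrays of control, arsenate and 30 µM phosphate had the lowest estimated array weights of their groups (0.64, 0.35 and 0.43).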

How the results depend on the processing

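The alternatives without the replicate 1 arrays, for features with means under 15, without pseudogene and organelle loci and with pseudogene loci were chosen after seeing the data, and the others before. Counts at a minimum difference of 1 log2 unit were 2119 (arsenate 8 h), 224 (30 µM phosphate), 592 (1 mM phosphate), 2724 (arsenate against 30 µM phosphate), 444 (1 mM against 30 µM phosphate) and 4508 (arsenate 1.5 h), lower by construction. With array weights 30 µM phosphate gave 2377 calls, and without the replicate 1 arrays 1876. The overexpressor comparison gave 0 calls on the compared groups only, 5690 with array weights and 12 with the replicate block, where the count of features higher with arsenate and lower in the overexpressor went from 0 to 1. The replicate block moved no other count by over 1.5 times, and apart from WRKY42, the glutathione S-transferase, silencing and DNA damage lists it changed no call among the named genes and fixed lists. Leaving out single arrays gave 4274 to 5375 calls for arsenate at 8 h, 259 to 911 for 30 µM phosphate, 1247 to 1707 for 1 mM phosphate, 5842 to 7247 for arsenate against phosphate, 680 to 1885 between phosphate doses, 8959 to 12759 for arsenate at 1.5 h and 0 to 105 for the overexpressor. A group left with fewer arrays borrows its spread from the others. The correlation of arsenate and 30 µM phosphate effects ranged from -0.016 to 0.15. An estimated correlation took the lists that passed from 11 to 1 with arsenate and from 5 to 0 in the overexpressor. The transposable element median with arsenate at 1.5 h (-0.18 to -0.12 on leaving out arrays) turned to 0.60 with pseudogene loci. In the overexpressor it turned from 0.01 (0.0036 to 0.019 on leaving out arrays) to -0.0048 with quantile normalization, -0.028 with median centring, -0.17 with Sadhu loci and -0.30 with pseudogene loci. Median centring turned PHT1;4 to 0.02, SPX1 to 0.03 and the phosphate starvation list to 0.02 with arsenate, and in the overexpressor PHT1;1 to -0.03, PHT1;4 to -0.01, PHO1 to -0.02 and the phosphate starvation list to -0.024. None of these values in the overexpressor passed. There, on leaving out single arrays, PHT1;1 ranged from -0.01 to 0.04, PHO1 from -0.09 to 0.13, WRKY75 from -0.26 to 0.06 and the phosphate starvation list from -0.015 to 0.039. PHT1;1 was 0 without overexpressor replicate 1 and -0.01 without overexpressor replicate 3 or wild-type replicate 1 or 2. PHO1 was -0.09 without overexpressor replicate 3, -0.02 without wild-type replicate 1 and -0.05 without wild-type replicate 2. WRKY6 was 0.03 with array weights and 0.01 without overexpressor replicate 2, WRKY75 was 0.06 without overexpressor replicate 3, and the phosphate starvation list was -0.015 without wild-type replicate 2. The genes given alternatives are those the text names, a choice made after a longer table was seen. Of the values of named genes and the phosphate starvation list under the alternatives, 1264 kept direction and side of the threshold, 31 lost the call, 21 gained it and 18 changed sign. The cause of these changes was not tested. The phosphate starvation list at 8 h and the overlap between 1.5 h and 8 h were not run. On NimbleGen, 1683 features lay near the top of the scale on all arrays, where differences are compressed.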

Other observations

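All tests in this part were chosen after the values were seen, except the counts over splits of the arrays. The tests of overexpressor replicate 2 as a wild-type array and of the ONSEN loci were each the last of several versions, and values of the earlier ones are also given.

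With arsenate at 1.5 h, 8 pseudogene loci rose more than every other locus of that class: AT1G11265, AT1G21945, AT1G48710, AT1G58140, AT3G32415, AT3G59720, AT3G61330 and AT5G13205. From background knowledge, not from the reference table, they are copies of ONSEN, a copia-type retrotransposon known for its activation by heat. AT1G48710 rose by 2.42 ± 0.27 (adjusted p = 0.00042) and AT1G11265 by 2.34 ± 0.16 (adjusted p = 2.8e-05). The median of the 8 was 2.25, with 2.18 to 2.31 above the control mean on the 3 wild-type arsenate arrays and 1.23, 2.07 and 1.65 on the overexpressor arrays. Near-identical copies share probes, so the 8 features are not independent. Among other classes, 29 of 151 microRNA features were lower and 7 higher, and 7239 of 30891 protein-coding features were lower and 4334 higher.

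These 8 loci were noticed because they led the class on the wild-type arrays, so their position was not tested against chance. A component that varies between arrays and acts alike on loci of like level is argued against: with the class ranked without 1 control array, the 8 highest loci, 6 to 7 of them the same, lay 0.66 to 1.43 above loci of like level on each overexpressor array against that control. The ranking used wild-type arsenate arrays. Across pseudogene loci their difference from control followed the deviation of overexpressor replicate 2 from its group with r = 0.88. The ranking could thus pick loci on which a component between arrays is strong, and the gap does not argue for a response to arsenate. A component acting more strongly on these loci stays open. It was fitted with the median of loci of like level as a covariate, over overexpressor arrays and the controls, which served in the picking. The term for arsenate was 1.21 (95% interval 0.69 to 1.74), but 1.12 (-0.22 to 2.47) without overexpressor replicate 1. In this term and in the gaps on overexpressor arrays, arsenate and genotype changed together, so their effects cannot be separated. In earlier versions the ONSEN median lay 1.28, 0.64 and 1.09 above loci of like level on the overexpressor arrays, and on replicate 1 the lowest locus lay 0.22 above the highest control and 0.55 of the rise was kept. A response to arsenate also stays open, and signal from probes shared between copies was not tested.

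Pseudogene, tRNA and mitochondrial loci were higher with arsenate at 1.5 h. A normalization shift at their signal level is argued against for tRNA and mitochondrial loci. Their gaps to protein-coding features of the same control level were 1.43 and 0.89. Between the quartiles of their control level, pseudogene loci differed by 0.65 and protein-coding features by 0.11, a gap of 0.54. From a control level of 9.55 upwards pseudogene medians were 1.02 to 1.33 and protein-coding ones -0.36 to -0.06, which argues against a shift there. Up to 8.48 they were 0.12 to 0.28 and 0.05 to 0.14. Differences near the floor are compressed, so a shift stays open for the dimmest pseudogene loci. A component that varies between arrays of 1 treatment is a candidate explanation: across pseudogene loci, the deviation of control replicate 2 from the other controls followed that of overexpressor replicate 2 from the others of its group with r = 0.83 (0.49 across protein-coding loci). Both are replicate 2, same-numbered arrays of these groups correlated over all features (0.63 for this pair), genes are not independent replicates, and wild-type arsenate replicate 2 was not raised in this class (0.56 against 0.63 and 0.64). The arsenate difference in wild type also followed that deviation of overexpressor replicate 2. The r was 0.88 across pseudogene, 0.78 across tRNA, 0.9 across mitochondrial and 0.21 across protein-coding loci. A response of the plants to arsenate stays open, with p = 0.15 with an estimated correlation.

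The 3 overexpressor arrays differed over the same classes. Less arsenate reaching the plants of replicate 1 is argued against by the rises of protein-coding features. That array kept a median of 1 of them, against 0.95 and 0.92 on replicates 2 and 3. Of the falls it kept 0.73, against 0.88 and 0.74, so the falls argue less clearly. A wild-type sample in place of overexpressor replicate 2 is argued against: of 9 features (8 loci) that set replicates 1 and 3 apart from all wild-type arrays by over 1 log2 unit, it lay beyond every wild-type array by over 0.5 for 100%, against at most 2 of 11 features for a held-out wild-type array. With features set apart by over 0.5, it did so for 15 of 42 and a held-out wild-type array for at most 11 of 70, and in an earlier version, by the nearer side, 52.4% and at most 32.9%. Across all features, however, replicate 2 lay nearer the wild-type arsenate arrays (r = 0.9934 to 0.9966) than overexpressor replicates 1 and 3 (0.9804 and 0.9911). The argument thus rests on few loci. A lowering of the class by WRKY6 overexpression stays open (p = 0.1 with an estimated correlation).

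For each comparison the 6 arrays were also split in all 10 ways. In each, 1 split, the real one, reached the real count: 5469 calls for arsenate at 8 h, 880 for 30 µM phosphate, 2311 for 1 mM phosphate, 7088 for arsenate against 30 µM phosphate, 2246 between phosphate doses, 14517 for arsenate at 1.5 h and 4 for the overexpressor. The highest other split gave 1 call for 30 µM phosphate and 0 in each of the other comparisons. With 10 splits no share under 0.1 can be reached.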
